A study of Rattus norvegicus with 9 samples.

How the data were processed

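The series compared gene expression in the thoracic aorta of rats born to diabetic mothers with that of rats born to control mothers. RNA of 1 animal from each group was labelled with Cy3 and Cy5 and hybridised together to a two-colour Agilent array, per the labels, and each deposited table holds 22575 features. The 9 arrays analysed here came from 5 pairs of animals, named below by the number of the offspring of a diabetic mother. Pair 193 was set against control offspring 189, pair 194 against 190, pair 197 against 191, pair 199 against 192 and pair 220 against 216. Pairs 193, 197, 199 and 220 were hybridised in both dye orientations, and pair 194 in 1, with the offspring of the diabetic mother on Cy3. The series' design text counts 10 samples, and the tenth is not analysed here. Litter, sex and age of the animals are not given in the labels, so littermates among the 5 pairs would make p-values too small. All arrays carry a single date in the labels.

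The deposited values are 1 log ratio per feature and array. The authors' scanner software, background correction and normalization are not given in the sources used here. Centring was read from the values: the mean of every array was 0, and the median was 0.0096 and -0.0070 in the arrays of pair 193, -0.033 in pair 194, 0.088 and 0.046 in pair 197, 0.013 and -0.057 in pair 199 and 0.023 and -0.025 in pair 220, with the array that had the diabetic mother's offspring on Cy3 first. The base of the logarithm, and with it the scale, is not stated. The deposited values were taken as log2, so no fold changes are given. Signals and background flags were not used here, so dim features were not filtered, control spots stayed in, and the number of arrays limits the precision.

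The direction of the ratio is not stated either. The turning of dye-swapped arrays fixed before the data were examined was not applied, because the deposited values were taken as already turned to run one way. That reading was chosen after seeing them and is not stated in the sources used here. It rests on the 2 arrays of each swapped pair. Of the fixed list medians over 0.5 in size on either array, 12 of 12 had the same sign on both, and of those over 0.3, 25 of 26, with both sizes chosen after the values were seen. The adipocyte median was 2.83 and 2.55 in pair 197 and 2.21 and 2.42 in pair 199, against -0.074 and -0.28 in pair 193 and 0.036 and -0.075 in pair 220. Over 0.5, the same sign was held by 2 of 2 medians in pair 193, 3 of 3 in pair 197, 5 of 5 in pair 199 and 2 of 2 in pair 220. In unturned arrays these would be dye effects, yet the adipocyte medians did not recur in pairs 193 and 220 on the same dyes. Nor did the heat shock medians of pair 220 (1.23 and 1.13) recur in pair 193 (-0.23 and -0.32). For these lists in pairs 197, 199 and 220, this argues against unturned arrays. Values of the arrays with the diabetic mother's offspring on Cy5 nearly all had more than 6 digits, and the others 6 or fewer, so the former were written differently. Features over 1.5 in size mostly had opposite signs on the 2 arrays of pair 199, which unturned arrays and a dye effect would both give. Arrays of different pairs were more alike in the same dye orientation, which a dye effect and unturned arrays would both give. If the arrays were not turned, the test of the dye effect would hold the group comparison, so the group comparison, the lists and the named genes were computed again with the sign of the Cy5 arrays turned. The dye part of a swapped pair, that is 0.5 of the difference between its 2 arrays, correlated with that of each other swapped pair at r from 0.137 to 0.579 across features, and with the single array of pair 194 at r from 0.0425 to 0.175. Arrays of different pairs had a mean r of 0.142 in the same dye orientation and -0.074 in opposite ones. Features are not independent, and these correlations do not decide between the readings. Whether a positive value means higher in offspring of diabetic mothers or of control mothers stays unknown, and signs are given below as deposited. If the direction is the reverse, every sign below turns together. If the arrays were not turned, the group comparison, the fixed lists and the named genes change as given under the other reading. For most named genes only a change in the sign of the mean is given, so a gene not listed there may still shrink. The spreads of the pairs, the far pairs, the leading genes of each pair and the lists added later were not computed for it.

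All gene names rest on a numbering of the features chosen after seeing the data. The platform's annotation gives 1 gene symbol for 12750 features, several for 5 and none for 9820. With the row numbers as deposited, probes of the same gene did not follow each other. With swapped arrays averaged, r was taken over the values of the 5 animal pairs, so a single r is imprecise. Over 136 pairs of probes with ratios among the largest, its median was 0.224, against up to 0.274 in 20 random orders. Reading the annotation as numbered down the columns of the grid of 215 rows and 105 columns, with rows and columns reversed, gave a median r of 0.798 over 150 such pairs, and 39.3% of them had r over 0.9. The highest value among the other 7 layouts was 0.279, and among 8 shifts of the used layout by 1 row or column 0.263. In each of the 9 arrays the probes of a pair correlated at 0.479 to 0.685 under the used numbering and at -0.112 to 0.189 as deposited. Further layouts and offsets had been searched before this one was chosen. The choice was made on probe pairs, and the gene lists described below give a separate check: the mean r between adipocyte markers was 0.767 under the used numbering and -0.0149 as deposited, and 19 of 26 lists had a higher mean r under the used numbering. Of the named probes, 12720 matched the RefSeq table (assembly GRCr8) by gene ID, and no symbol changed. No genome build is named for the array, so no coordinates are given.

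Probes of 1 symbol were averaged, which left 19478 features, of them 9653 gene symbols. Dye-swapped arrays of the same extracts are technical repeats and were averaged, so that 5 pairs entered as 5 replicates. The pairing comes from the animal numbers in the labels; as a check, deviations from the mean of each dye orientation correlated within a pair at 0.373 (pair 193), 0.708 (197), -0.127 (199) and 0.195 (220). The main test was the intercept of limma's lmFit with eBayes (limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. All adjusted p-values come from limma. Alongside, list means were tested by an exact two-sided sign-flip test over the 5 pairs, which cannot give a p below 0.0625; adjusted over the lists, its smallest p was 0.738. The dye effect was tested with limma on the dye parts of the 4 swapped pairs. The agreement of dye-swapped arrays was described by Pearson's r.

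A set of 27 gene lists with 364 entries was fixed before the data were examined, as were the tests, the thresholds, the rule for named genes and the alternatives listed first below; 293 entries were measured. Lists were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry; a list needed 3 measured members, which left 26. One older list symbol was followed to its current name. The rule for named genes took features past the threshold with 1 sign in all 5 pairs, at most 15 per direction. Where fewer than 10 passed, it filled up to 10 per direction with the features of 1 symbol and 1 sign in all 5 pairs that had the smallest unadjusted p. It added up to 4 members of each list described in detail, by smallest p, and Ptgir. The 12 lists described in detail were chosen after all values, and the far pairs among members of every list, had been seen; the far pairs of the wider set are given with the closing results.

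Both tests were tried on simulated data with the fitted spread of the 5 pairs. With 50 of 19478 features shifted at each size, 30% were called at a shift of 0.5, 92% at 1 and 100% at 2 and at 3, with 12 false calls. In the simulation of lists, a list shifted by 0.5 was called in 20 of 20 runs, and 1 of 500 tests of unchanged lists made a call. Variances were drawn from the fitted prior after a first version, which drew them from each feature's moderated variance, had given more false calls. Genes in the simulation varied independently, unlike those of a tissue.

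The alternatives fixed before the data were examined were centring each array on its median, scaling arrays to a common median absolute deviation, fitting all 9 arrays with a dye term and the pair as a block, subtracting the dye effect from pair 194, leaving out each pair, keeping probes separate, a robust prior, array weights, leaving out the 119 features with an exact 0, a term for the 2 series of slide numbers (4 and 5 arrays), other thresholds, no moderation and a 1.5-fold filter. Added after seeing the data were the subtraction of the median of the 15 by 15 features around each feature, testing only features with a gene symbol, leaving out pairs 197 and 199, the adipocyte mean as a covariate, turning the sign of the arrays with the diabetic mother's offspring on Cy5, naming lists by the deposited row numbers, and an estimated correlation together with leaving out pairs, taken for lists only. The adipocyte list's own value under the adipocyte covariate is 0 by construction and was left out, and with deposited row numbers, which attach names to other features, only the count of lists was taken. Pairs 197 and 199 were picked for their high adipocyte means. The covariate lay near 0 in the other pairs, so its fit leans on the same pairs as leaving out 197 and 199. These 2 settings are thus not separate checks. A test of ribosomal protein genes against fat content was run and then withdrawn, because it averaged pairs chosen by a measured outcome. In the fits of all 9 arrays, lists were tested on limma's moderated statistics (cameraPR).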

Results

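Thoracic aortas of rats born to diabetic mothers were compared on two-colour arrays with aortas of rats born to control mothers, 1 animal of each group per array. The 9 arrays held 5 pairs of animals, 4 of them in both dye orientations. Values are log ratios with an unstated base, taken as log2. Which group a positive value stands for is not settled by the sources used here, so the 2 sides are called positive and negative, as deposited. The values of dye-swapped arrays were taken as already turned to run one way, which the sources used here do not state. The spread of the ratios differed between pairs, with an SD over features of 0.212 in pair 193, 0.384 in pair 194, 0.449 in pair 197, 0.342 in pair 199 and 0.252 in pair 220. Features over 1 in size numbered 110, 355, 827, 288 and 97 in these pairs. Pair 194 was measured on 1 array and the others are means of 2, so these spreads do not compare like with like: the single arrays of pair 199 had an SD of 0.51 and 0.57 over all features before probes were averaged, and that of pair 194 had 0.39.

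The comparison of the groups asked whether maternal diabetes during pregnancy left a mark on gene expression in the aorta of the offspring. The genes with the same sign in all 5 pairs and the smallest p were, on the negative side, Zbtb8a, which encodes a zinc finger protein (-0.89 ± 0.33, mean ± SD, n = 5 pairs), Naa35, a subunit of an N-terminal acetyltransferase (-0.86 ± 0.32), and Vcam1, a leukocyte adhesion molecule of endothelium (-0.66 ± 0.28). On the positive side they were Ephx1, microsomal epoxide hydrolase (0.45 ± 0.098), Rps13, a protein of the small ribosomal subunit (0.48 ± 0.17), and Ppa1, an inorganic pyrophosphatase (0.55 ± 0.24). None of these passed the threshold, since limma gave all of them an adjusted p of 0.926. The ranking holds for the values as deposited, and none was made with the sign of the Cy5 arrays turned. The 2 arrays of pair 193 had opposite signs for Zbtb8a (0.42 and -1.58, with the diabetic mother's offspring on Cy3 first) and Naa35 (0.50 and -1.35), as did those of pair 199 for Ephx1 (1.06 and -0.035).

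Other genes named on the positive side were Naca (0.39 ± 0.12), which binds nascent polypeptides, the imprinted gene Nnat (1.09 ± 0.69), the G protein subunit Gng11 (0.56 ± 0.29), the Mediator subunit Med31 (0.42 ± 0.17), the tetraspanin Tspan13 (0.41 ± 0.16), the ribosomal protein gene Rps10 (0.37 ± 0.11) and Sox17, an endothelial transcription factor (0.36 ± 0.10). Nnat ranged from 0.081 in pair 220 to 1.90 in pair 193. On the negative side followed the adenylyl cyclase Adcy7 (-0.52 ± 0.24), Nol3, a repressor of apoptosis (-0.43 ± 0.18), the histone demethylase Kdm3a (-0.45 ± 0.22), the sarcoglycan gene Sgca (-0.34 ± 0.083), Lsp1 (-0.55 ± 0.32), Armcx1 (-0.73 ± 0.48) and the potassium chloride cotransporter Slc12a4 (-0.56 ± 0.35). These values too did not pass. The 2 arrays had opposite signs for Naca in pairs 193 (-0.22 and 0.996) and 220 (-0.097 and 1.01). Of the 20 genes, 11 had opposite signs on the 2 arrays of at least 1 pair, in 14 of 80 combinations of gene and swapped pair, 8 of them in pair 193. The 2 probes of Adcy7 differed, at -0.067 and -0.97, as did those of Sox17, at 0.61 and 0.11, and of Sgca, at -0.10 and -0.57. For these genes the single sign held for the mean of the probes only. The weaker probe was at 0.054 in pair 193 for Adcy7, at -0.18 in pair 194 for Sox17 and at 0.042 in pair 197 for Sgca.

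**Figure D1:**
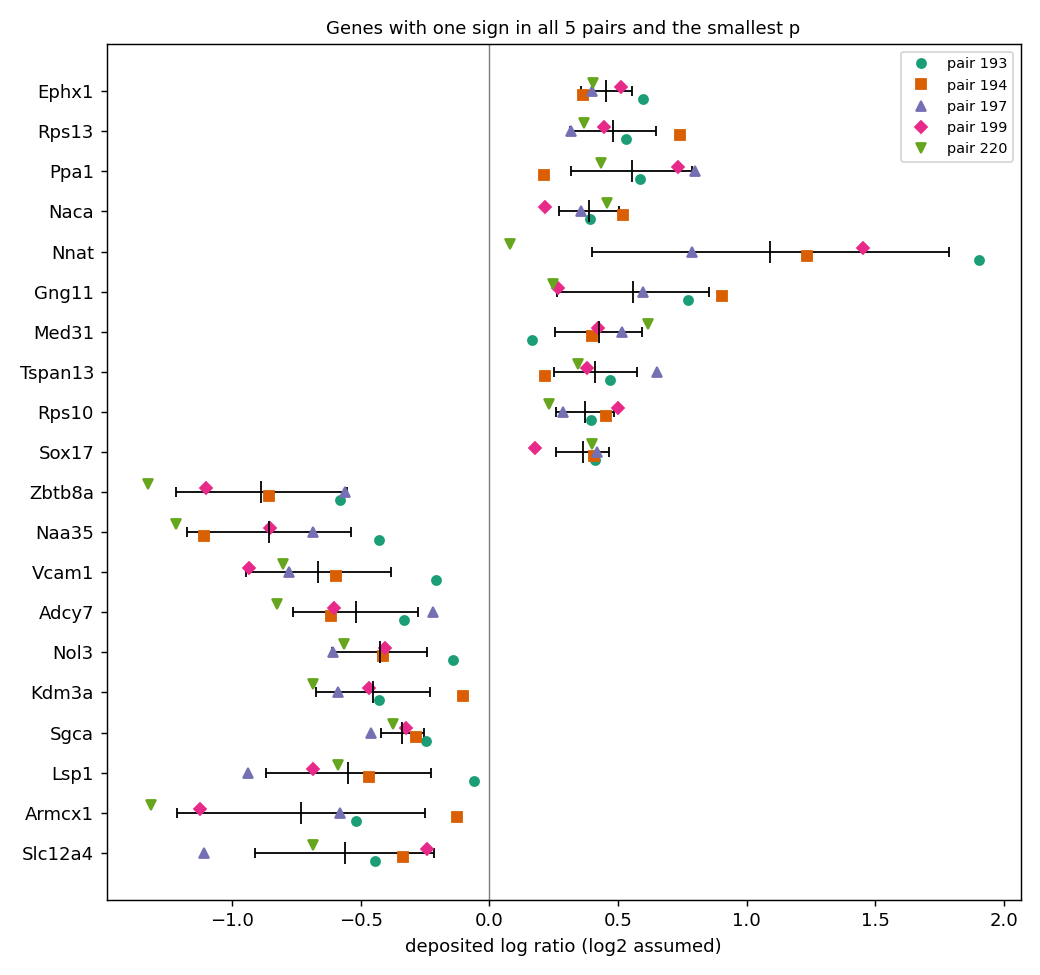
The 20 genes, 10 on each side, with 1 sign in all 5 pairs and the smallest p, on a horizontal axis of the deposited log ratio (log2 assumed), with coloured symbols for the 5 pairs of animals and black bars for the mean ± SD over pairs. Vcam1 lay between -0.93 and -0.21, and none of the 20 passed adjustment.

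No feature passed an adjusted p of 0.05 in limma, of 19478 tested. An unadjusted p under 0.05 was reached by 929 features, 435 positive and 494 negative, where 974 would be reached by chance; without pair 199 it was reached by 612. The same sign in all 5 pairs was held by 1199 features, or 6.16%, against 6.25% by chance. With the sign of the Cy5 arrays turned it would be 19.97%, a share that a dye effect common to the pairs would raise as well. Without moderation, 1 feature passed, the ribosomal protein gene Rps23 (0.19 ± 0.0051, adjusted p = 0.00262), named here after its value was seen. Its spread over the pairs was very small, and limma gave it an adjusted p of 0.926.

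Prostanoid genes were one of the fixed lists, and the prostacyclin receptor Ptgir was named in advance. It was at 0.11 ± 0.27 over the 5 pairs (adjusted p = 0.943 in limma), with values of 0.072, 0.45, 0.32, -0.16 and -0.15 in pairs 193, 194, 197, 199 and 220. Its sign followed the dyes: all 5 arrays with the diabetic mother's offspring on Cy3 were positive (0.23 to 0.75) and all 4 with it on Cy5 were negative (-0.70 to -0.11). With the sign of the Cy5 arrays turned, as if they had not been turned before deposit, Ptgir would be at 0.41 ± 0.10 and positive in 5 of 5 pairs (limma adjusted p = 0.136). If the arrays were turned before deposit, a dye effect of its probe would give these opposite signs. Turning them again would then make the dye effect look like a difference between groups. If the arrays were not turned, a dye effect would give the same sign on all arrays. Opposite signs would then be what a difference between groups gives. The values of Ptgir cannot tell these readings apart, and Ptgir passed in neither. No conclusion on a difference between groups is thus drawn from the turned value. Prostacyclin synthase Ptgis was at -2.57 in pair 197 and between -0.66 and 0.15 in the others, and the thromboxane receptor Tbxa2r was at -0.38 ± 0.55. The prostaglandin receptors Ptgdr and Ptger4 were at -0.094 ± 0.067 and 0.19 ± 0.43. Of 14 measured prostanoid genes, 4 had positive and 10 negative means, and none passed over all features or adjusted over the list alone. The list mean was -0.085 ± 0.11 (adjusted p = 0.322 by camera).

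Adipocyte markers had the largest mean of the 27 lists, at 0.91 ± 1.42 (SD, n = 5 pairs), and passed the camera test (limma adjusted p = 6.41e-06; with an estimated correlation, adjusted p = 0.628). The difference lay in 2 pairs: the list mean was 2.70 in pair 197 and 2.22 in pair 199, but -0.14, -0.15 and -0.075 in pairs 193, 194 and 220. Adipsin (Cfd) was at 2.74 and 2.83 in pairs 197 and 199, the lipid droplet gene Cidec at 1.51 and 1.71, hormone-sensitive lipase (Lipe) at 1.82 and 2.36, and the adipogenic receptor Pparg at 1.37 and 1.25. In pair 194 the mean averaged members of both signs, with Cfd at 1.06 and Ucp1 at -2.19. Of 12 measured members 11 had positive means, and none passed over all features or adjusted over the list alone. The adjusted p ranged from 1.30e-09 to 0.858 over 15 alternatives, and the exact sign-flip test gave an unadjusted p = 0.5. Without both of these pairs, which were picked for their high values, the mean was -0.12.

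Fatty acid oxidation genes were high in the same 2 pairs as the adipocyte markers. Their list mean was 0.77 in pair 199 and larger in pair 197, against -0.32 to 0.024 in the other pairs, and 0.28 ± 0.57 in all (camera adjusted p = 0.0364; with an estimated correlation, adjusted p = 0.628). Hadhb, of the mitochondrial trifunctional protein, was at 2.19 and 2.85 in pairs 197 and 199, the carnitine palmitoyltransferase Cpt1b at 3.20 and 2.33, the dehydrogenase Acadm at 2.15 and 1.86 and Acadvl at 0.88 and 0.83. Of 14 members 13 had positive means and none passed over all features or adjusted over the list alone. The call also ended without pair 197 (mean 0.096, adjusted p = 0.627), without pair 199 (mean 0.15, adjusted p = 0.177), with scaled arrays (mean 0.18, adjusted p = 0.151) and with symbols alone (mean 0.28, adjusted p = 0.0701; range 0.000383 to 0.858 over 16 alternatives). The mean turned without both pairs (-0.13) and with the adipocyte covariate (-0.082). These 2 settings lean on the same pairs and are not separate checks. As pairs 197 and 199 were picked for their high adipocyte values, the turn does not test a cause.

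Contractile smooth muscle genes lay on the negative side, at -0.25 ± 0.50 (camera adjusted p = 0.0364; with an estimated correlation, adjusted p = 0.628). Pairs 193 and 197 carried this, with list means of -0.54 and -0.97, while the others lay between -0.10 and 0.21. The myosin light chain gene Myl9 was at -0.91 and -1.92 in pairs 193 and 197, the integrin gene Itga8 at -1.58 and -2.25, and Tagln, an actin-binding protein, at -0.75 and -0.71. Calponin (Cnn1) was at -0.29 ± 0.48 over all pairs. Of 13 members 11 had negative means, and none passed over all features or adjusted over the list alone. Acta2, Myh11 and Mylk of the fixed list were not among the measured members. The call also ended without pair 193 (mean -0.17, adjusted p = 0.209), without pair 197 (mean -0.068, adjusted p = 0.525), without pairs 197 and 199 (mean -0.16, adjusted p = 0.206) and with the adipocyte covariate (mean -0.14, adjusted p = 0.239; range 0.00344 to 0.719 over 16 alternatives). With centred arrays it ended at about the same mean (mean -0.25, adjusted p = 0.0664). In pair 197 it stood beside the adipocyte mean of 2.70.

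Elastic fibre genes were also negative, at -0.21 ± 0.24 in the list mean (camera adjusted p = 0.00567; with an estimated correlation, adjusted p = 0.628), with 4 of 5 pairs below 0. In pair 199 the list mean was -0.061 but the median 0.0079, so that mean did not stand for most members. Elastin (Eln) was at -1.31, -1.53 and -1.33 in pairs 197, 199 and 220, and at -0.041 and 0.28 in pairs 193 and 194, where the value of pair 193 is the mean of 1.23 and -1.31 on its 2 arrays. The crosslinking enzyme Loxl1 was at -0.39 ± 0.39, its relative Lox at -0.16 ± 0.17 and the latent TGF-beta binding protein Ltbp2 at -0.68 ± 0.92. Of 14 members 12 had negative means, and none passed over all features or adjusted over the list alone. The call also ended with the adipocyte covariate (mean -0.13, adjusted p = 0.139; range 0.000478 to 0.702 over 16 alternatives) and without pair 197 (mean -0.12, adjusted p = 0.247), in which the list mean was -0.59 and the adipocyte mean the largest. Without both pairs high in adipocyte markers, 197 and 199, the list passed at the preset correlation (mean -0.14, adjusted p = 0.0396), but not with an estimated one (adjusted p = 0.76). The unadjusted exact sign-flip p was 0.125.

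Endothelial markers were positive, with a list mean of 0.16 ± 0.24 (camera adjusted p = 0.0364; with an estimated correlation, adjusted p = 0.628) and 3 of 5 pairs above 0. It was 0.29, 0.20, 0.47, -0.14 and -0.0072 in pairs 193, 194, 197, 199 and 220, and was thus highest in pairs 193 and 197, where contractile genes were at -0.54 and -0.97 and adipocyte markers at -0.14 and 2.70. The VEGF receptor Kdr was positive in each pair, at 0.40 ± 0.38, and endomucin (Emcn) was at 0.42 ± 0.56, the tight junction gene Cldn5 at 0.32 ± 0.47 and the angiopoietin receptor Tek at 0.15 ± 0.20. Of 10 members 9 had positive means, and none passed over all features or adjusted over the list alone. The call also ended without pair 193 (adjusted p = 0.137), 194 (0.0954) or 197 (0.38, with a mean of 0.085). It also ended with the dye effect of pair 194 subtracted (mean 0.14, adjusted p = 0.0709), separate probes (mean 0.097, adjusted p = 0.127), symbols alone (mean 0.16, adjusted p = 0.0701) and the adipocyte covariate (mean 0.15, adjusted p = 0.195; range 0.000774 to 0.628 over 16 alternatives).

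**Figure D2:**
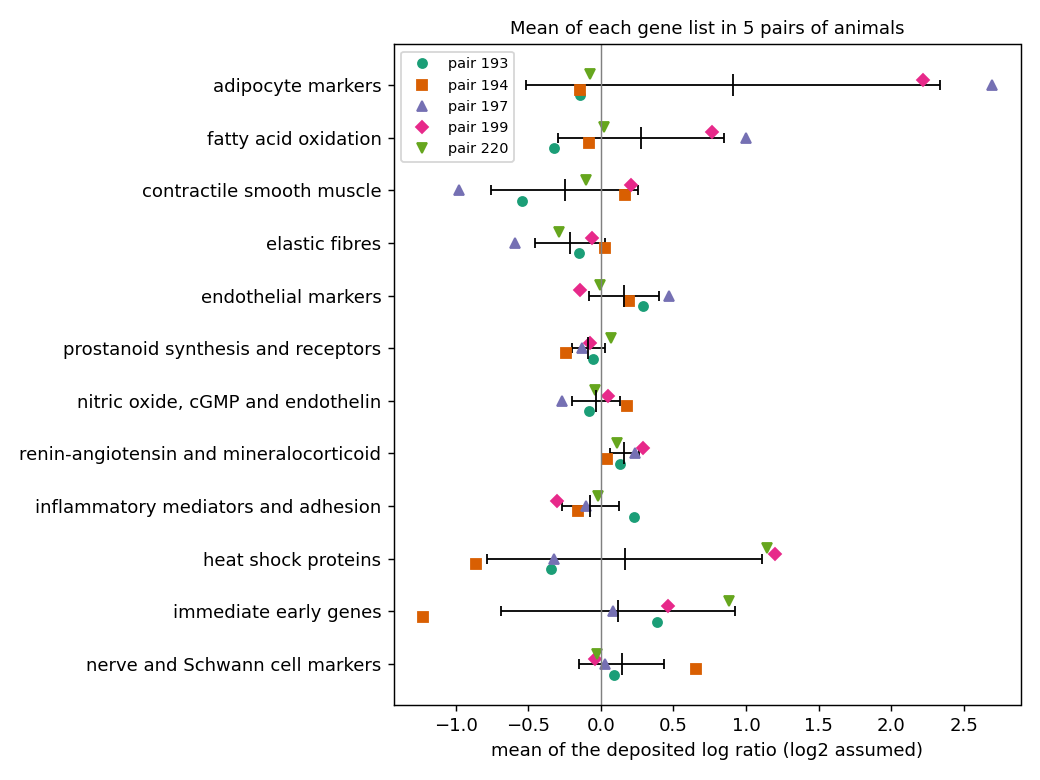
Means of the 12 gene lists described in detail, on a horizontal axis of the mean deposited log ratio of the list members (log2 assumed), with coloured symbols for the 5 pairs and black bars for the mean ± SD over pairs. Adipocyte markers lay at 2.70 and 2.22 in pairs 197 and 199 and within 0.15 of 0 in the others.

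The renin-angiotensin list was positive in all 5 pairs, with a mean of 0.16 ± 0.10, but missed the threshold (camera adjusted p = 0.0733, exact sign-flip p = 0.0625 unadjusted, the smallest that 5 pairs allow, and 0.738 adjusted over the lists). With the dye effect of pair 194 subtracted it passed camera (adjusted p = 0.0437; range 0.0437 to 0.871 over 16 alternatives), and with an estimated correlation and all else as reported the adjusted p was 0.628. The list median was also positive in each pair, but in pair 199 it was 0.013 against a mean of 0.29. List medians on the 2 arrays had opposite signs in pair 193 (-0.035 and 0.14) and pair 199 (0.14 and -0.11). Here the array with the diabetic mother's offspring on Cy3 is given first. Angiotensinogen (Agt) was at 0.71 ± 0.76, with 1.13 and 1.84 in pairs 197 and 199, where adipocyte markers were high as well. The receptor genes Agtr1b and Agtr2 were at 0.16 ± 0.24 and 0.19 ± 0.34, and the converting enzyme Ace at 0.14 ± 0.35. Nitric oxide, cGMP and endothelin genes were at -0.032 ± 0.17 (adjusted p = 0.697), with the endothelin-converting enzyme Ece1 at 0.46 ± 0.53 and the guanylate cyclase subunit Gucy1a1 at -0.60 ± 0.80. Prkg1 and Pde5a of the same list were at 0.15 ± 0.11 and -0.17 ± 0.32. No member of either list passed over all features or adjusted over the list alone.

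In the list of inflammatory mediators and adhesion molecules, Vcam1 was the 1 member that passed when adjusted over the list alone, and none passed over all features. Each of the 27 lists was adjusted alone at 0.05, with no adjustment over lists, so chance alone could give such a call in 1 of them. Vcam1 was negative in 5 of 5 pairs in the values as deposited. Its 2 arrays were at -0.15 and -0.26 in pair 193, -0.89 and -0.67 in pair 197, -0.98 and -0.89 in pair 199, and -0.78 and -0.83 in pair 220. With the sign of the Cy5 arrays turned, the 2 values of each of these pairs would largely cancel. Its single sign over the pairs thus does not carry over to that reading. Of the other members, Nfkb1 was at 0.14 ± 0.070, the chemokine gene Ccl2 at -0.34 ± 0.59 and Irf1 at -0.19 ± 0.45, and the list mean was -0.071 ± 0.20 (adjusted p = 0.322). The 2 probes of Nfkb1 differed, at 0.67 and -0.25 in pair 199 and at 0.0018 and 0.38 in pair 194. Its small SD thus holds for the mean of the probes only. Leaving out 1 pair gave ranges of -0.51 to -0.12 for Ccl2 (weakest without pair 199), -0.33 to -0.063 for Irf1 (weakest without pair 194) and -0.15 to -0.013 for the list (weakest without pair 199), and all 3 were strongest without pair 193. The leukocyte marker list was at -0.087 ± 0.20 (adjusted p = 0.322), and leaving out 1 pair gave -0.15 (without pair 193) to -0.021 (without pair 194).

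Heat shock and immediate early genes differed widely between pairs. The heat shock list had means of 1.20 and 1.15 in pairs 199 and 220, -0.86 in pair 194, -0.35 in pair 193 and -0.32 in pair 197, and did not pass (0.16 ± 0.94, adjusted p = 0.322). Hspa1a, the inducible HSP70, was at 3.20 and 2.99 in pairs 199 and 220 and at -2.03 in pair 194. Dnajb1 was at 1.51, 1.44 and -1.50 and the constitutive Hspa8 at 0.72, 0.47 and 0.050 in pairs 199, 220 and 194, with Hsp90aa1 at 0.23 ± 1.10 over all pairs. Immediate early genes, switched on within minutes of a stimulus, had a list mean of -1.23 in pair 194 and of 0.085 to 0.89 in the others (0.12 ± 0.81, adjusted p = 0.514). Without pair 194 their mean was 0.46 and passed camera (adjusted p = 9.90e-05; range 9.90e-05 to 0.989 over 16 alternatives), but not with an estimated correlation (adjusted p = 0.584 without pair 194 and 0.807 with it). Nr4a1 ranged from -0.74 in pair 194 to 1.61 in pair 220, Ier2 from -0.62 to 0.87, Zfp36 from -0.59 to 0.065 and Junb from -0.28 to 0.70. No member of either list passed over all features or adjusted over the list alone.

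Nerve and Schwann cell markers stood apart in pair 194, at a list mean of 0.66 against -0.042 to 0.093 in the others (0.14 ± 0.29 over all, adjusted p = 0.322). The myelin gene Pmp22 was at 3.77 and the Schwann cell transcription factor Sox10 at 1.15 in that pair, which was measured on 1 array. Tyrosine hydroxylase (Th) and neuropeptide Y (Npy) were at -0.47 and -0.19 there. No member passed over all features or adjusted over the list alone.

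The other lists did not pass. Means were negative for collagens and their processing (-0.16 ± 0.19, adjusted p = 0.0816), matrix proteases and inhibitors (-0.11 ± 0.088, 0.322), TGF-beta and BMP signalling (-0.098 ± 0.20, 0.322), skeletal muscle markers (-0.098 ± 0.14, 0.322), ion channels and calcium handling (-0.072 ± 0.18, 0.373), cardiac muscle markers (-0.057 ± 0.20, 0.612), clock genes (-0.051 ± 0.18, 0.697) and interferon response genes (-0.043 ± 0.23, 0.38). Means were positive for oxidant and antioxidant enzymes (0.14 ± 0.23, 0.0626), MHC class II (0.11 ± 0.21, 0.191), insulin, IGF and glucose uptake (0.11 ± 0.15, 0.322), cell cycle (0.020 ± 0.10, 0.648) and fibroblast and adventitia markers (0.0066 ± 0.24, 0.995). The clock and fibroblast lists had medians of the opposite sign, at 0.011 and -0.0050, and camera's direction for the fibroblast list was negative. The mean of matrix proteases was negative in all 5 pairs (exact sign-flip p = 0.0625 unadjusted and 0.738 adjusted over the lists). Their list median, however, was 0.058 in pair 199 and 0.011 in pair 220, and negative in the other pairs. The negative means of pairs 199 and 220 thus did not stand for most members. The ion channel mean lay mostly in pair 197 (-0.36) and was -0.00072 without it. In pair 197 the median of this list was 0.11, so its mean there did not stand for most members. Erythroid markers had 2 measured members, at a mean of 0.017 ± 0.13, and were not tested. Of these lists no member passed over all features or adjusted over the list alone.

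Collagens, oxidant enzymes and MHC class II passed camera under some alternatives, all at the preset correlation. With an estimated correlation and all pairs their adjusted p was 0.628, 0.628 and 0.643. Collagens passed with all 9 arrays and the pair as a block (adjusted p = 0.0243) and without pair 194 (0.0288; range 0.0243 to 0.858 over 16 alternatives). Oxidant and antioxidant enzymes passed with the block (0.019) and without pair 193 (0.0167), 194 (0.0396) or 220 (0.0326; range 0.0167 to 0.989 over 16 alternatives), and MHC class II passed without pair 199 (0.0323; range 0.0323 to 0.858 over 16 alternatives). With an estimated correlation the adjusted p was 0.584 for collagens without pair 194, 0.664, 0.707 and 0.559 for oxidant enzymes without pairs 193, 194 and 220, and 0.551 for MHC class II without pair 199. For the fit with the block the correlation was not estimated. Oxidant enzymes were high in the pairs high in adipocyte markers, at 0.31 and 0.45 in pairs 197 and 199 against -0.091, -0.0066 and 0.019 in pairs 193, 194 and 220. Their mean was -0.026 without these 2 pairs and -0.0017 with the adipocyte covariate, 2 settings that are not separate checks.

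Lists past the threshold with the preset correlation of 0.01 were thus 5: adipocyte markers, fatty acid oxidation, contractile smooth muscle, elastic fibres and endothelial markers. With an estimated correlation camera called 0 of 26 lists, with 1 at an unadjusted p under 0.05, and fry called 0, also with 1. Without pair 197 the count was 1, the adipocyte list. Without both pair 197 and pair 199, left out after seeing the data, it was 2, endothelial markers and elastic fibres, and 0 with an estimated correlation, with 0 at an unadjusted p under 0.05. With the sign of the Cy5 arrays turned, also added after seeing the data, camera called 0 lists, with 1 at an unadjusted p under 0.05, and the means of adipocyte markers (-0.024), contractile (0.057) and elastic fibre genes (0.066) changed side.

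A dye effect was tested in the 4 pairs with both orientations. No feature passed an adjusted p of 0.05 in limma (smallest 0.131), but 4082 features had an unadjusted p under 0.05, where 974 would be reached by chance. The absence of single calls in 4 pairs thus does not mean that there was no dye effect. If the arrays were not turned before deposit, this test would hold the group comparison. With the Cy5 arrays turned and pair 194 added, no feature passed in limma (smallest adjusted p 0.117) and 3131 had an unadjusted p under 0.05. The dye effect was larger in size than the mean ratio of these pairs for 54.5% of features. The 2 arrays of a pair correlated across features at r = 0.15 in pair 193, 0.674 in pair 197, -0.176 in pair 199 and 0.0715 in pair 220, where features are not independent replicates. Of features over 1.5 in size on either array, 67.5% in pair 193, 89.0% in pair 197, 33.5% in pair 199 and 70.2% in pair 220 had the same sign on both arrays.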

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

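In this part, the medians of the second fat and second heat shock lists were tested as written before they were seen, and all other tests were chosen after the result was seen. Of 95 list means and named genes, 5 had 1 pair far from the other 4, where chance gives about 1 in 20, or 4.75. Nerve and Schwann cell markers (list mean 0.66), Pmp22 (3.77) and Sox10 (1.15) were far from the rest in pair 194. Agtr2 (0.78) and Sox17 (0.18, against a mean of 0.41 in the other pairs) were far from the rest in pair 199. The value of Agtr2 there is the mean of 0.076 and 1.48 on its 2 arrays, so it rests on 1 of them. The 95 leave out members of 15 lists, a choice made after the wider result had been seen. With up to 4 members of every list, 12 of 153 had a far pair, against 7.65 by chance. The further genes were Serpinf1 (-1.14) and Ckm (-2.21) in pair 197, Lyz2 (1.18) in pair 193, RT1-Ba (-0.33) and Sod1 (0.97) in pair 199, and Nox4 (-0.65) and Actn3 (-0.62) in pair 194.

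Adipocyte markers differed in 2 of 5 pairs. In the other 3 pairs the list mean reached at most 0.146 in size. This argues against a difference on the same side and of like size in every animal pair. In pair 194, however, that mean averaged members of both signs, with Cfd at 1.06 and Ucp1 at -2.19. It thus does not show that fat genes were alike in the 2 animals of pair 194. Dye bias is argued against by the 2 arrays of each of pairs 197 and 199, whose list medians differed by at most 0.103 of their mean. It is also argued against by pairs 193 and 220, on the same dyes, where those medians were near 0. Perivascular fat carried with the aorta is a candidate explanation: a second list, of which 16 fat genes were measured and 0 were in a fixed list, had a median of 1.34 in pair 197 and 1.41 in pair 199 and of -0.40 to 0.077 in the others, with G0s2 at 3.87 and 3.10 and Adrb3 at 3.36 and 2.96 in pairs 197 and 199. Several of these genes are also expressed outside fat, and the labels do not settle how the aortas were cleaned. A change in the animals' own fat in these 2 pairs, with or without maternal diabetes, stays open and was not tested.

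Heat shock and immediate early genes differed between pairs in both directions. Dye bias is argued against by pairs 199 and 220, as in 2 of 2 swapped pairs with a heat shock median over 0.5 in size both arrays had the same sign, if the arrays were turned before deposit. For stress or handling of single animals, the median of a second heat shock list had the same sign in 2 of 3 such pairs (0.43 in pair 199 and 0.25 in pair 220). In pair 194 its median was 0.073 against -0.72 in the fixed list, while its mean there was -0.10. By the bound set before this result was seen, the opposite sign of the median counted against the explanation. That explanation is left undecided here only because the median lay within its standard error over members of 0.16, a condition added after the result was seen. A second immediate early list had medians of -0.21 in pair 194 and 0.28 in pair 220, and an effect of maternal diabetes that differs between animals was not tested.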

How the results depend on the processing

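Settings that left out pairs 197 and 199, used the adipocyte covariate, subtracted the local median, turned the sign of the Cy5 arrays, took only features with a symbol or used deposited row numbers were added after seeing the data. No feature passed in limma in any setting, including all 9 arrays with the pair as a block (0, smallest adjusted p 0.229) and with the slide series as a further term (0, 0.155), except without moderation (1) and at an unadjusted p (929); with the Cy5 arrays turned the smallest adjusted p was 0.117. The count at unadjusted p under 0.05 ranged from 612 to 1249 when 1 pair was left out (612 without pair 199). It was 450 with symbols alone, where fewer were tested, 514 without pairs 197 and 199, 458 with the covariate, 89 with the 1.5-fold filter, 3131 with the Cy5 arrays turned and 1196 with the block. Lists past the threshold numbered 1 to 7 when 1 pair was left out (1 without pair 197), 3 with symbols alone, 2 without pairs 197 and 199, and 0 with the covariate, the Cy5 arrays turned, an estimated correlation, fry or deposited row numbers. With the block 7 passed, and no list beyond collagens and oxidant enzymes changed its call. The cause of these changes was not tested.

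Further calls were lost by contractile genes with centred arrays (mean -0.25, adjusted p = 0.0664), endothelial markers with the dye effect of pair 194 subtracted (mean 0.14, adjusted p = 0.0709) and with separate probes (mean 0.097, adjusted p = 0.127), and fatty acid oxidation with scaled arrays (mean 0.18, adjusted p = 0.151), against means as reported of -0.25, 0.16 and 0.28. The renin-angiotensin list passed with the dye effect subtracted (0.0437), and oxidant enzymes with separate probes (0.0316) and local medians (0.0336), all at the preset correlation. With an estimated one and all else as reported they did not pass (adjusted p = 0.628 and 0.628). With pairs left out and an estimated correlation, also added after seeing the data, camera called 0 lists in each case, with at most 1 at an unadjusted p under 0.05 and a smallest adjusted p of 0.551.

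List means turned sign without pairs 197 and 199 for adipocyte markers (-0.12), fatty acid oxidation (-0.13), fibroblast markers (-0.15), nitric oxide genes (0.020), inflammatory genes (0.017), oxidant enzymes (-0.026), clock genes (0.0040), heat shock proteins (-0.019) and cardiac markers (0.090). With the covariate, which leans on the same pairs and is not a separate check, this held for fibroblast markers (-0.13), nitric oxide genes (0.022), inflammatory genes (0.00047), oxidant enzymes (-0.0017), fatty acid oxidation (-0.082), clock genes (0.0053) and cardiac markers (0.071). Fibroblast markers also turned with scaled arrays (-0.030), separate probes (-0.0046) and local medians (-0.017). Leaving out 1 pair moved 24 of 26 list means and 39 of 68 named genes by over 1.5 times. It turned the sign within ranges of -0.055 to 0.075 for fibroblast markers, -0.084 to 0.028 for nitric oxide genes, -0.094 to 0.030 for interferon response, -0.10 to 0.0097 for clock genes, -0.072 to 0.46 for immediate early genes, -0.095 to 0.42 for heat shock proteins, -0.0092 to 0.049 for the cell cycle and -0.098 to 0.0024 for cardiac markers. With the Cy5 arrays turned, list means changed sign for contractile genes (0.057), fibroblast markers (-0.032), nitric oxide genes (0.031), renin-angiotensin genes (-0.014), ion channels (0.0027), elastic fibres (0.066), matrix proteases (0.021), MHC class II (-0.015), adipocyte markers (-0.024), insulin and IGF genes (-0.030), clock genes (0.096), immediate early genes (-0.20), heat shock proteins (-0.13), cell cycle (-0.062) and cardiac markers (0.16). The cause was not tested.

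Of the named genes, the sign turned without pairs 197 and 199 for Hadhb (-0.10), Cpt1b (-0.39), Acadm (-0.28), Acadvl (-0.090), Ptger4 (-0.00094), Dnajb1 (-0.057) and Junb (-0.036). Leaving out 1 pair gave ranges of -0.035 to 0.72 for Dnajb1, -0.089 to 0.56 for Hsp90aa1, -0.21 to 1.10 for Hspa1a, -0.024 to 0.22 for Junb and -0.049 to 0.96 for Pmp22. With the Cy5 arrays turned, the sign changed for Naca (-0.20), Tspan13 (-0.036), Zbtb8a (0.039), Lsp1 (0.057), Armcx1 (0.33), Slc12a4 (0.20), Cpt1b (-0.13), Itga8 (0.096), Eln (0.34), Ltbp2 (0.018), Tbxa2r (0.35), Ptger4 (-0.057), Gucy1a1 (0.14), Pde5a (0.0026), Agtr1b (-0.15), Agtr2 (-0.035), Dnajb1 (-0.33), Hsp90aa1 (-0.059), Hspa1a (-0.30), Ier2 (-0.075) and Npy (-0.061). The 68 named genes passed in none of the settings run for them. The median r of dye-swapped arrays was 0.111, and -0.067 by Spearman's rho. With features over 0.5 in mean size it was 0.674, a filter that favours arrays of the same sign. Signals over background were not used here, so the limit they set is unknown.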

Other observations

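All tests in this part were chosen after the results were seen, and so was the rule for the genes named next: in each pair, the 10 named genes per side with the largest ratio on the weaker of its arrays. Pair 197 was led on the positive side by Pck1 (5.28), a gene of glyceroneogenesis, the brown fat uncoupling protein Ucp1 (4.84), G0s2 (3.87), lipoprotein lipase Lpl (3.74) and Cidea (3.49), and pair 199 by Hspa1a (3.20), G0s2 (3.10), Ces1d (3.27), adiponectin Adipoq (3.28) and Pck1 (3.28). On the negative side, pair 197 was led by Lmcd1 (-3.02), Nexn (-2.78), smooth muscle gamma-actin Actg2 (-2.80), the myosin phosphatase inhibitor Ppp1r14a (-2.68) and Cpe (-2.56). Of these, Lmcd1 (-3.27), Nexn (-1.74), Actg2 (-1.49) and Cpe (-1.42) were also among the 10 in pair 193, whose adipocyte list mean was -0.14. The positive side of pair 193 was led by the acute phase gene Serpina3n (3.14), Nnat (1.90) and the phospholipase Pla2g2a (1.67), and Serpina3n was at 2.30 in pair 220.

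Pair 194, measured on 1 array, was led by the sodium channel gene Scn7a (5.29), Sostdc1 (4.40), Art3 (4.19), Apod (3.80) and Pmp22 (3.77), several of them known from Schwann cells. Its negative side held the immediate early genes Fos (-3.50), Ccn1 (-3.25), Atf3 (-2.32) and Egr1 (-1.95), with Ucp1 (-2.19) and Cox8b (-2.16) of brown fat and Hspa1a (-2.03). In pair 220, Atf3 was at 2.45 and Egr1 at 1.51, and that pair was led by Nr4a3 (3.52) and Hspa1a (2.99) and held elastin (-1.33) and Lyz2 (-1.29) on its negative side.

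Ribosomal protein genes were sought as a group because Rps13 and Rps10, 2 of its 47 measured members, were among the named genes, so its values are not independent evidence. The mean was 0.15 ± 0.15, with 0.29, 0.18, -0.063, 0.27 and 0.054 in pairs 193, 194, 197, 199 and 220, and 35 members had positive means, 16 positive and 1 negative had an unadjusted p under 0.05, 0 passed over all features and 4 adjusted over the list alone. The group passed camera (limma adjusted p = 4.53e-10 over this and 3 other lists chosen after seeing the data), but not with an estimated correlation (adjusted p = 0.284) or by fry in one direction (adjusted p = 0.26), while fry in either direction gave an adjusted p of 0.00551. Dye bias of pair 194 is argued against, since the mean was 0.139 without it. Of the 16 ways to turn the signs of the pairs, 3 gave a mean as large (exact p = 0.188, highest other value 0.173), which are too few ways for a share under 0.05, and an effect of maternal diabetes on these genes was not settled.

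The count at unadjusted p under 0.05 was 929, and the highest in another of the 16 ways to turn the pairs was 2007, with pairs 194 and 199 turned; 7 ways gave as many, the real one included. The count of lists past the threshold was 5, the highest other 8, and 9 ways gave as many. These counts thus did not set the real signs apart from the other ways to turn the pairs. With 16 ways a share under 0.05 cannot be reached in any case.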
